A study of Schmidtea mediterranea with 100 samples.

How the data were processed

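Cells of the asexual CIW4 strain of the planarian flatworm Schmidtea mediterranea were dissociated, stained with Hoechst (for DNA) and pyronin Y (for RNA) and sorted by FACS, per the labels. There were 100 samples. For 4 gates, called RNA-low, G1, S/G2/M and PM, 1 bulk library each was made from Trizol-extracted RNA with a TruSeq kit, and 96 single cells of the RNA-low gate were made into libraries with Smart-seq2, which uses no molecular identifiers. The labels do not spell out PM, and that name is used here as given. The animals, pools and plates behind the samples are not named in the labels, so the 96 cells of the RNA-low gate count as 1 sample.

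Both tables hold whole-number read counts per transcript, not normalized, as deposited by the authors. The tools bcl2fastq 1.8.3 and Bowtie2 are named in the submitters' processing notes, without a version for Bowtie2. The counting tool, the filters and the transcript reference are not given in the sources used here, so reads of near-identical transcripts could have been divided between them in ways that cannot be traced. The bulk table has 67386 transcripts, of which 163 carry a gene name. The single-cell table has 38237, of which 135 carry a name and 2395 are not listed in the bulk table. No genome, annotation or table of gene names was given, so the remaining transcripts are known by identifier alone. All 100 columns were used. The bulk column headed G0 was taken as the RNA-low library, because the 96 columns of the RNA-low single-cell table also begin with G0 and the other 3 bulk columns carry the names of their gates. The marker levels were not used for that step.

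The bulk libraries held 57385665 counted reads in RNA-low, 54070578 in G1, 74968402 in S/G2/M and 47338591 in PM. The number of transcripts per read count peaked not at 1 read but at about 5 reads in RNA-low, 9 in G1, 21 in S/G2/M and 25 in PM. There were 922, 466, 363 and 416 transcripts at 1 read and 1866, 1090, 519 and 520 at the peak, with as few as 922, 369, 137 and 81 at a count below it. Each starting fragment was therefore taken to have been read about that often, which is a rough estimate, and dividing the totals by the peak gave an estimated 11477133, 6007842, 3569924 and 1893544 fragments. Intervals on estimated fragments are wider than those on reads and are the ones printed.

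Libraries were scaled by trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3 and expressed as CPM, in which the counts of each library are set to the same scaled total. All levels are relative to a scaled library and are not amounts per cell. A similar or higher CPM in RNA-low does not mean as much or more transcript per cell. Transcripts with at least 5 CPM in either gate of a comparison were kept. The log2 ratio was taken after adding 0.5 CPM to each level. A transcript was called higher or lower when the ratio was at least 2-fold and the exact 95% conditional binomial interval on reads excluded equality. Calls on estimated fragments were fewer in comparisons with PM. They gave 1853 higher and 2499 lower for RNA-low, 936 and 1868 for G1, and 2808 and 3220 for S/G2/M. For S/G2/M against G1 they gave 1499 and 2168, and the other comparisons were unchanged. With 1 library per gate no difference has a replicate check, no test across conditions was possible and no p is given. All intervals cover counting error only, and intervals of a ratio are of the CPM without the added 0.5. A level of 0 reads was set to a floor of 3 fragments of that library for a fold bound, which can exceed the limit given by the 95% interval.

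The gene lists, cell type markers, comparisons and thresholds were fixed before the data were examined, except for the early epidermal progeny list. For that list the plan named prog-1, prog-2 and a few relatives. The 18 members used also hold other prog-1 and prog-2 family members named in the tables. Of 27 planned lists, 14 had no named member in the tables, among them ribosomal proteins, translation factors and the TOR pathway. The 13 others had 41 named members. The lists used were pan-neoblast, S phase and replication, G2 and mitosis, chromatin and PIWI pathway, ribosomal RNA, early epidermal progeny, gamma (intestinal) neoblast, epidermis, neuron, muscle, intestine, cathepsin-positive and parenchymal, and secretory. After the names in the tables had been seen, 6 further lists were added, namely Mediator, Hedgehog pathway, Wnt pathway, cilia and intraflagellar transport, developmental transcription factors, and RNA-binding regulators. A list was described by its median log2 ratio and, with 3 or more kept members, by the percentile of that median among 10000 random lists of the same size drawn from 50 bins of mean expression. The percentile describes these libraries and is not a test. In each comparison with RNA-low, the genes named were piwi-1, up to 4 members of each planned list with the largest absolute log2 ratio, and up to 8 other named genes in each direction among those with at least 50 CPM in the higher gate. Genes named beyond this rule were chosen after their values were seen, as were the genes drawn in the plots and those named in comparisons without RNA-low.

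Single cells with at least 500 detected transcripts were kept, which left 79 of 96. The 17 cells left out served as the measure of background, since the plate has no labelled empty wells. Shares of cells have exact Clopper-Pearson 95% intervals. A list of at least 3 measured markers counted as present in a cell with 2 or more of them, and a shorter list with 1. Cells were clustered on log2(CPM + 1) of the 1000 most variable transcripts with 10 principal components and Ward linkage, with the number of clusters from 2 to 6 set by the mean silhouette. No doublet caller was run on these 96 sorted cells. For a further set of shares, cells were thinned to 50000 reads other than ribosomal RNA, which left 73 kept cells and 15 of the cells left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

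The comparison step was tested on simulated libraries with 200 changed transcripts. Among transcripts changed by 1.5 on the log2 scale it recovered 100% for RNA-low against G1 (11376 transcripts), 99% for RNA-low against S/G2/M (11150 transcripts) and 94% for RNA-low against PM (12220 transcripts), and all of those changed by 3. Unchanged transcripts called apart numbered 4 of 11176, 28 of 10950 and 187 of 12020. For G1 against PM the recovery at 1.5 was 98% with 242 of 12111 unchanged transcripts called, for S/G2/M against PM 98% with 351 of 11909, and for S/G2/M against G1 99% with 64 of 10995. These counts are for intervals on reads. The simulated libraries shared the same mean levels and varied by counting alone. The counts therefore do not show how many calls between the real libraries are false. In 79 simulated cells of 2 groups the clustering gave 4 clusters. None of them mixed the groups, and 2 were single cells, with 1882 and 6800 reads, far below the 222016 of the next cell. The 200 changed transcripts were raised by 3 on the log2 scale in the first group and lowered by 3 in the second. Reads of the simulated cells varied by counting alone. Such groups are easy to separate, so the result does not show how well the real cells were divided. Alternatives changed the scaling, filter, pseudocount, fold threshold, cell filter, detection threshold, thinning, clustering settings and the summary over cells. Alternatives added after the data were seen used intervals on estimated fragments, totals without ribosomal RNA, cells with at least 10000 reads other than ribosomal RNA, clustering without ribosomal RNA, and the tables without transcripts present in at least 50% of the cells left out.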

Results

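The series profiled planarian cells sorted by DNA and RNA content, and its title names slow-cycling neoblasts that respond to TOR signalling as the subject. Neoblasts are the dividing stem cells of the adult planarian. One bulk library was available for each of 4 gates, RNA-low, G1, S/G2/M and PM, together with 96 single cells from the RNA-low gate. The bulk libraries held 47338591 to 74968402 counted reads over 67386 transcripts, and 13992 of these reached 5 CPM in at least 1 gate. The single cells had a median of 986484 reads, from 1882 to 7719585. Every bulk difference rests on 1 library per gate and has no replicate check.

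The 4 gates differed in the relative abundance of stem cell, cell division and progeny transcripts. The summed pan-neoblast transcripts (piwi-1, piwi-2 and piwi-3, which encode PIWI proteins, and the RNA-binding protein gene bruli) were highest in S/G2/M at 10246 CPM, followed by RNA-low at 7439, G1 at 5725 and PM at 3399. The replication genes PCNA and mcm2 together reached 647 CPM in S/G2/M and 168 in G1, against 49.9 in RNA-low and 49.5 in PM. CyclinB2, which encodes a mitotic cyclin, stood at 249 CPM in S/G2/M, 74.8 in G1, 39.5 in RNA-low and 30.1 in PM. The early epidermal progeny family prog-1 and prog-2, expressed by cells that have left the neoblast state for the epidermis, was highest in G1 at 29657 CPM and lowest in RNA-low at 1860, with 20171 in PM and 6405 in S/G2/M. Its members are close relatives, and levels of single members are uncertain because the counting could have divided their reads. RNA-low had the second highest pan-neoblast sum and the lowest epidermal progeny sum of the 4 libraries.

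Other markers were spread over the gates. The epidermal marker vim-1 was highest in PM at 112 CPM, against 16.5 in G1, 10.7 in S/G2/M and 2.02 in RNA-low. The muscle gene titin was also highest in PM, at 12.9 CPM, and was below 5 CPM in the other gates. The neuronal regulators COE and elav-2 together were highest in RNA-low at 139 CPM, against 47.3 in G1, 38.0 in PM and 17.6 in S/G2/M. The intestine list (porcnA and porcn-B) varied little, from 103 CPM in PM to 165 in S/G2/M. The single measured secretory marker, a mucin, was below 5 CPM in all 4 gates. Ribosomal RNA took 16.9% of reads in RNA-low, 16.8% in G1, 21.9% in S/G2/M and 35.1% in PM. Of 39 planned markers at 5 CPM or more, 39 kept their highest gate with median-of-ratios scaling and 36 with library totals.

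**Figure D1:**
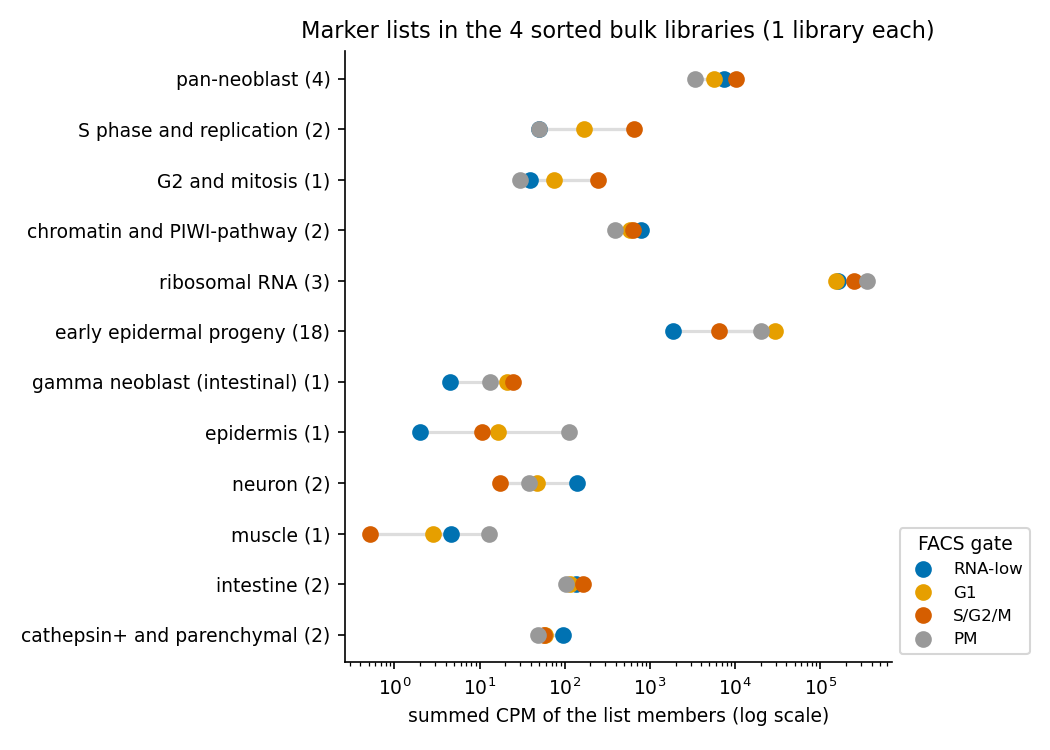
Summed CPM of the planned marker lists in each bulk library, on a log axis, with 1 point per FACS gate and the number of members at 5 CPM or more in brackets. RNA-low lies lowest for early epidermal progeny (1860 CPM) and highest for the neuron list (139 CPM), and S/G2/M lies highest for the replication and mitosis lists.

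RNA-low against G1 asked how cells of low RNA content differed from the G1 gate. Relative to the scaled libraries, neoblast transcripts stood at similar levels, with piwi-1 at 1594 CPM in RNA-low and 1309 in G1 (log2 ratio 0.28, interval 0.25 to 0.32). All 18 early epidermal progeny transcripts were called lower in RNA-low. Their sum was 15.9-fold lower, and their median log2 ratio of -3.97 lay below all 10000 random lists. The replication genes were also lower, mcm2 at 9.12 against 68.2 CPM (log2 ratio -2.84, interval -3.22 to -2.60) and PCNA at 40.7 against 99.4 CPM (-1.28, interval -1.46 to -1.11). In the other direction, COE stood at 76.1 against 19.8 CPM (1.92, interval 1.67 to 2.21) and elav-2 at 63.4 against 27.5 CPM (1.19, interval 0.97 to 1.44).

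None of the 4 pan-neoblast genes differed by 2-fold between RNA-low and G1. Their log2 ratios ran from -0.39 for bruli to 0.56 for piwi-3, with piwi-2 at 0.40, and the median of 0.34 lay at percentile 85.7. CyclinB2 was at -0.91, short of 2-fold. Of the chromatin and PIWI pathway list, chd4, which encodes a chromatin remodeller, was at 0.75 and the Tudor gene tdrd112 at -0.30. Among the progeny, prog-1h stood at 0.118 CPM in RNA-low against 72.5 in G1, prog1g was at 0.505 against 49.0 CPM and prog-1j at 0.421 against 23.8 CPM. For prog-1e there were 0 reads in RNA-low against 27.8 CPM in G1, which was 110-fold lower at the floor of 3 fragments. The epidermal marker vim-1 (log2 ratio -2.75) and the gamma neoblast marker, given as NXK2.2_Dth-1 (-2.10), were lower in RNA-low as well.

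Outside the planned lists, among named genes with at least 50 CPM in the higher gate, those highest in RNA-low over G1 were hb-2, a transcription factor (log2 ratio 2.31), and the gap junction gene innexin-1 (1.95, at 59.5 against 15.1 CPM). The next were below 2-fold, from Kif3B (0.80) and dvl-b (0.79) through a spondin transcript (0.73), ptc (0.71) and Med12 (0.65) to smoothened (0.59). Reticulocalbin-1 was the one gene of this group called lower, at 197 against 537 CPM (-1.44), followed below 2-fold by Med23 (-0.86), PAX5-1 (-0.69), nemo (-0.13) and Ku80 (-0.13). Of the cathepsin-positive list, NKX2.1_Dth-2 was at 0.57, and NKX2.1 was called higher at 18.1 against 6.49 CPM (1.41). NKX2.1 reads were also present in all 96 single cells, including the 17 left out for few transcripts. The intestine genes porcnA (0.36) and porcn-B (-0.03), mitochondrial 16S ribosomal RNA (-0.04) and both 28S ribosomal RNA transcripts (0.31 and 0.71) were not called.

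Over the 11890 transcripts kept, 2010 (16.9%) were called apart, 847 higher and 1163 lower in RNA-low. Among the 112 named ones, 16 were higher and 28 lower. Library totals with or without ribosomal RNA moved the median of all transcripts by -0.08, within 0.1, and the share of higher calls from 42.1% to 35.4% and 35.3%. A filter of 50 CPM turned the balance, to 208 higher and 176 lower.

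RNA-low against S/G2/M compared the low-RNA gate with the gate of replicating and dividing cells. The replication and mitosis genes were far lower in RNA-low, with mcm2 at 9.12 against 201 CPM (log2 ratio -4.39, interval -4.77 to -4.17), PCNA at 40.7 against 446 CPM (-3.44, interval -3.61 to -3.30) and CyclinB2 at 39.5 against 249 CPM (-2.64, interval -2.82 to -2.49). The neoblast genes were split. Both piwi-1 (1594 against 3640 CPM, -1.19) and bruli (-1.46) were called lower, while piwi-2 (-0.21) and piwi-3 (0.19) were not called. The chromatin remodeller gene chd4 went the other way, at 611 CPM in RNA-low against 92.2 (2.72, interval 2.56 to 2.90), as did COE (3.30) and elav-2 (2.57).

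The median of the pan-neoblast list was -0.70, at percentile 16.5 of the random lists. With library totals piwi-1 was at -0.96, short of 2-fold, and piwi-2 turned to 0.02. The PIWI pathway gene tdrd112 was lower in RNA-low (-1.53), opposite to chd4. Of the 18 early epidermal progeny transcripts 15 were lower and none higher, with a median of -2.10 below all random lists. Named by their log2 ratio with the added 0.5 CPM, which weighs heavily at such low levels, were prog-1e, prog1g (-6.55), prog-1j (-6.52) and prog-1h. Levels were 0 reads against 77.6 CPM for prog-1e and 0.118 against 38.9 CPM for prog-1h. At the floor set for 0 reads, prog-1e was 307-fold lower. The interval of its CPM ratio lay below -7.95 on the log2 scale. NXK2.2_Dth-1 (-2.33) and vim-1 (-2.15) were lower. NKX2.1, found in every single cell as described above, was higher (2.44), and NKX2.1_Dth-2 was not called (0.51). Neither intestine gene was called, with porcnA at -0.49 and porcn-B at 0.41, nor were the 16S (-0.83) and 28S (0.23 and 0.80) ribosomal RNAs.

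Among the other named genes, Med12 (3.24, at 127 against 13.0 CPM) and Med1 (2.48) of the Mediator complex, hb-2 (2.68), innexin-1 (2.45), NF1 (2.19), the Hedgehog receptor gene ptc (1.87), the RNA-binding gene mex3-1 (1.86, at 921 against 253 CPM) and castor (1.81) were called higher in RNA-low. The DNA damage kinase gene ATM (-1.64) and Med8 (-1.07) were called lower, and Med8 fell short of 2-fold with library totals (-0.84). Med7 (-0.93), Ku80 (-0.66), IQGAP (-0.10) and reticulocalbin-1 (-0.07) were below 2-fold, and the last 2 changed sign with library totals.

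Of 12040 transcripts kept, 4889 (40.6%) were called apart, 2710 higher and 2179 lower in RNA-low. This balance depended on the scaling. Median-of-ratios scaling, which moved the median of all transcripts by -0.17, gave 2280 higher and 2767 lower, while library totals, which moved it by 0.23, gave 3384 higher and 1543 lower. Totals without ribosomal RNA, a shift of 0.14, gave 3481 and 1930. Of 112 named transcripts 38 were higher and 28 lower with the main scaling.

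RNA-low against PM showed higher piwi-1 and lower early epidermal progeny transcripts in RNA-low, while markers of other lineages went both ways. Levels of piwi-1 were 1594 against 544 CPM (log2 ratio 1.55, interval 1.46 to 1.64), and piwi-3 was also called higher (2261 against 981 CPM) with the main scaling, with piwi-2 at 0.99 and bruli at 0.46 short of 2-fold. All 17 early epidermal progeny transcripts kept by the filter were lower, with a median of -3.59, and the sum over all 18 was 10.8-fold lower. The epidermal marker vim-1 stood at 2.02 against 112 CPM (-5.48, interval -6.47 to -5.18). The replication genes PCNA (0.15) and mcm2 (-0.48) and CyclinB2 (0.38) did not differ beyond counting error.

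The pan-neoblast median of 1.10 lay at percentile 98.5. Within the progeny family, prog-1b was at 0.606 against 63.9 CPM (-5.86), and prog-1h at -5.18. With 2 reads in RNA-low, prog-1d stood at 0.0337 against 12.9 CPM, and the interval of its CPM ratio lay below -5.25 on the log2 scale. At the floor set for 0 reads, prog-1e was 74.5-fold lower, and the interval of its CPM ratio lay below -5.82. Titin (-1.39) and NXK2.2_Dth-1 (-1.44) were lower, as was mitochondrial 16S ribosomal RNA (-1.37, at 13.3% against 33.0% of reads), whereas the 28S transcripts were at -0.53 and 0.74. COE (76.1 against 17.4 CPM) and elav-2 (1.60) were higher, and so was NKX2.1 (1.92), with its reads in every single cell. NKX2.1_Dth-2 (0.81), porcnA (0.44), porcn-B (0.33) and tdrd112 (0.77) were not called. The chromatin gene chd4 was called higher (1.10).

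Of the other named genes, innexin-1 (1.79), hb-2 (1.64), Med12 (1.27), activin-receptor-1 (1.15) and the beta-catenin gene Bcat-1 (1.02) were called higher in RNA-low. RIG-1L (0.99), mex3-1 (0.94) and ptc (0.92) were just short of 2-fold. Reticulocalbin-1 was called lower (-1.17), while PAX5-1 (-0.81) and Med23 (-0.19) were not called. With totals without ribosomal RNA, the ratios of piwi-3 (0.90), chd4 (0.80), Bcat-1 (0.72), activin-receptor-1 (0.85) and Med12 (0.98) were below 2-fold, and PCNA changed sign (-0.14).

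Of 13069 transcripts kept, 4415 (33.8%) were called apart, 1907 higher and 2508 lower in RNA-low. Totals without ribosomal RNA moved the median by -0.30 and gave 1207 higher and 3947 lower, while a filter of 50 CPM turned the balance to 592 higher and 329 lower. Of 116 named transcripts 24 were higher and 30 lower.

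**Figure D2:**
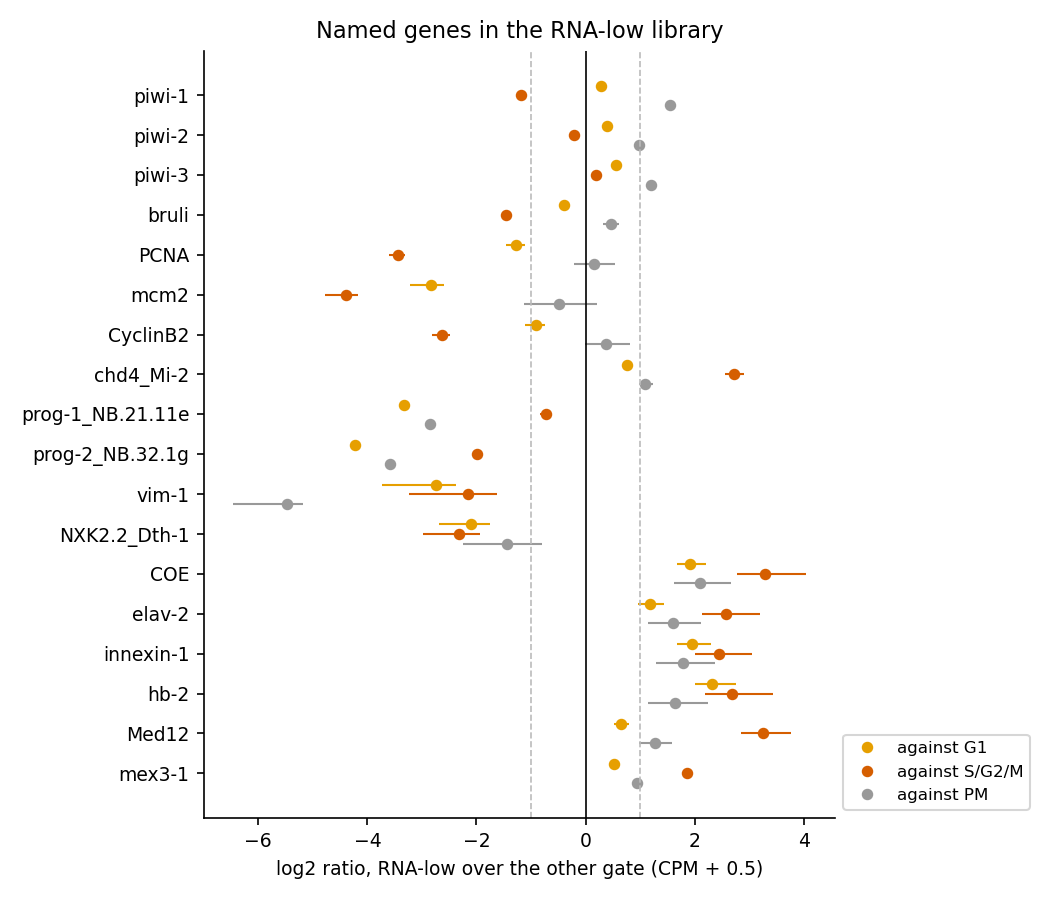
Log2 ratios of named genes in the RNA-low library over G1, S/G2/M and PM, with bars for the exact 95% interval on estimated fragments and dashed lines at 2-fold. Replication genes lie far below S/G2/M (mcm2 at -4.39), prog genes lie below all 3 gates, and COE lies above all 3, by 1.92 over G1.

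G1 against PM compared gates that both carried abundant progeny transcripts. The replication genes PCNA (99.4 against 36.6 CPM) and mcm2 (68.2 against 12.9 CPM) were higher in G1, with a median log2 ratio of 1.89, as was CyclinB2 (1.30). Of the pan-neoblast genes, piwi-1 alone was called higher in G1 (1309 against 544 CPM), and the list median was 0.75, at percentile 99.9. The early epidermal progeny median was 0.59, with 3 of 18 members higher and 1 lower in G1. The epidermal and muscle markers were lower in G1, vim-1 by -2.73 and titin by -1.99 on the log2 scale. In all, 2936 of 12953 transcripts (22.7%) were called apart, 1027 higher and 1909 lower in G1. Library totals, a median shift of 0.14, gave 1537 and 1733, and totals without ribosomal RNA, a shift of -0.21, gave 885 and 3072.

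S/G2/M against PM gave the widest separation of the 6 comparisons. All 4 pan-neoblast genes were called higher in S/G2/M, piwi-1 at 3640 against 544 CPM (log2 ratio 2.74), bruli at 806 against 212 CPM (1.92), piwi-2 at 3820 against 1662 CPM and piwi-3 (1.01), although piwi-2 (0.76) and piwi-3 (0.57) fell short of 2-fold with totals without ribosomal RNA. The replication genes had a median of 3.75 and CyclinB2 was at 3.02. Chd4 was lower in S/G2/M (-1.62) and tdrd112 higher (2.30). The early epidermal progeny family was divided, with 5 members higher and 11 lower in S/G2/M and a median of -1.58. Lower in S/G2/M were vim-1 (-3.33), titin (-3.72) and COE (7.29 against 17.4 CPM). Of 13002 transcripts, 6283 (48.3%) were called apart, 2926 higher and 3357 lower. Median-of-ratios scaling (shift 0.13) gave 3518 and 3056, library totals (-0.17) gave 2195 and 3729, and totals without ribosomal RNA (-0.44) gave 1632 and 5771. A filter of 50 CPM gave 1213 and 453.

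S/G2/M against G1 separated the cycling gate from G1 by the same replication and mitosis genes, PCNA (log2 ratio 2.16), mcm2 (1.55) and CyclinB2 (1.73). Of the pan-neoblast genes, piwi-1 (1.47) and bruli (1.07) were called higher in S/G2/M, and bruli fell to 0.75 with library totals. The early epidermal progeny median was -1.97, with 4 of 18 members higher and 10 lower in S/G2/M. COE and elav-2 were both lower (-1.38). Of 11895 transcripts, 3668 (30.8%) were called apart, 1499 higher and 2169 lower. Median-of-ratios scaling (shift 0.16) gave 2116 and 1814, library totals (-0.31) gave 758 and 3126, and totals without ribosomal RNA (-0.23) gave 1037 and 3233. A filter of 50 CPM gave 446 and 404.

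Most single RNA-low cells kept for analysis carried neoblast transcripts. Of the 79 cells kept, 70 (88.6%, interval 79.5 to 94.7) had reads of at least 2 of the 4 pan-neoblast genes, against 5 of the 17 cells left out. Reads of piwi-2 were found in 74 kept cells (93.7%, interval 85.8 to 97.9), piwi-3 in 57 (72.2%) and bruli in 35 (44.3%), against 4, 3 and 0 of the 17. PCNA, mcm2 or CyclinB2 were detected in 7 kept cells (8.86%, interval 3.64 to 17.4) and 1 cell left out. Other transcripts of similar or higher level in the RNA-low bulk library were also seldom read, such as COE in 1 and elav-2 in 6 kept cells, so this share does not show how many cells carried replication or mitosis transcripts. Cells were kept by their number of detected transcripts, so lower shares in the cells left out are expected for any expressed gene. Kept cells had a median of 2075 detected transcripts, from 531 to 7946, and 152963 reads other than ribosomal RNA. The cells left out had 389 transcripts and 88319 such reads. A single 28S transcript took a median of 76.5% of reads over all cells. A further 44 transcripts were read in at least 90 of the 96 cells, and took a median of 30.3% of reads other than ribosomal RNA in the kept cells and 86.2% in those left out. Apart from NKX2.1, hesl-3 and a spondin transcript, these 44 carry no gene name.

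**Figure D3:**
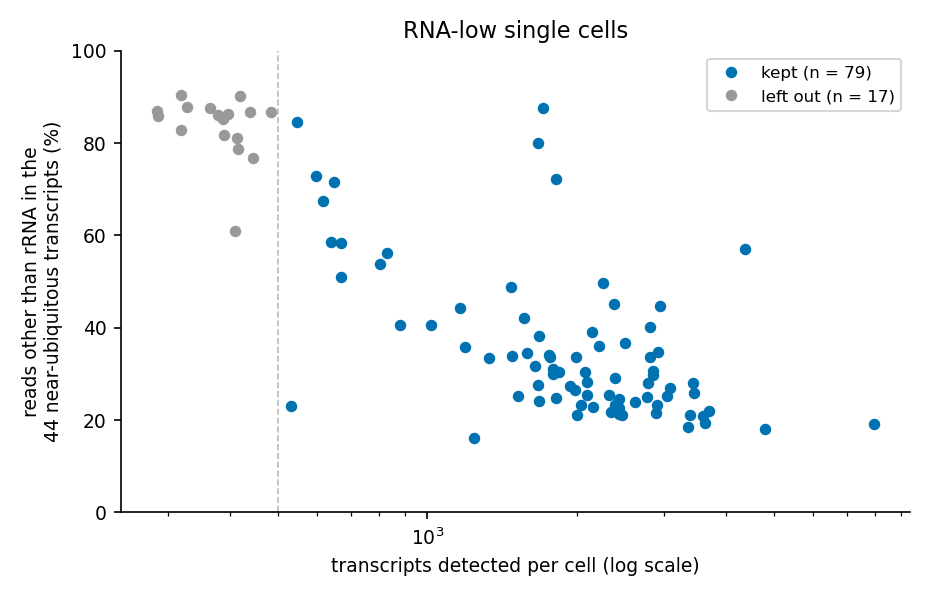
Percent of reads other than ribosomal RNA in the 44 transcripts found in at least 90 of 96 cells, against the number of detected transcripts on a log axis, with 1 point per RNA-low cell. The 17 cells left out, below 500 transcripts, have a median of 86.2% and the 79 kept cells 30.3%.

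Reads of piwi-1 were found in 51 kept cells (64.6%, interval 53.0 to 75.0) and 6 of the 17 left out (35.3%, interval 14.2 to 61.7), with a median of 52 reads in these kept cells and 5 in those left out. At 5 or more reads the numbers were 37 and 4. Thinned to 50000 reads other than ribosomal RNA, 44 of 73 kept cells and 5 of 15 left out had piwi-1, but the 44 transcripts read in nearly every cell count toward that depth, so the depth of the remaining reads was not matched. Chd4 was present in 54 kept cells (68.4%) and 1 cell left out, and mex3-1, named here after its values were seen, in 62 (78.5%) and 0. PCNA was found in 3 kept cells, mcm2 in 2 and CyclinB2 in 4, against 0, 0 and 1. The Tudor gene tdrd112 was found in 11 and in 0.

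For markers of other lineages the intervals of the kept cells overlapped those of the cells left out. With 17 cells left out these intervals are wide, reaching 28.7% for 1 cell of 17. Overlap was therefore hard to avoid for markers read in few kept cells, and it does not show that their reads are background. At least 2 early epidermal progeny transcripts were present in 52 kept cells (65.8%, interval 54.3 to 76.1) and 10 of the 17 left out (58.8%), and the family's most frequent members were prog-2_NB.32.1g (36 and 3 cells), prog2c (35 and 4), prog-2a (28 and 2) and prog2d (22 and 3). An intestine gene was found in 28 kept cells (35.4%) and 2 of those left out, with porcnA in 19 and porcn-B in 11 kept cells. Vim-1 was found in 15 and 1, mucin in 12 and 1, titin in 8 and 1, elav-2 in 6 and 0, COE in 1 and 0, NXK2.2_Dth-1 in 3 and 0, and NKX2.1_Dth-2 in 6 and 0. NKX2.1 was read in every cell of both kinds.

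Reads of piwi-1 together with a lineage list were counted in the 79 kept cells. Early epidermal progeny transcripts accompanied piwi-1 in 34 cells (43.0%, interval 31.9 to 54.7), with piwi-1 alone in 17, the progeny list alone in 18 and neither in 10. At 5 or more reads of each the share with both was 20.3%, and at 1 read both were also present in 4 of the 17 cells left out. The progeny list was present in 66.7% of cells with piwi-1 and 64.3% of those without against 58.8% of the cells left out. Both piwi-1 and an intestine gene were read in 19 cells, piwi-1 and vim-1 in 11, piwi-1 and mucin in 8, piwi-1 and titin in 6, piwi-1 and a neuron marker in 4, and piwi-1 and NXK2.2_Dth-1 in 2. The cathepsin-positive list accompanied piwi-1 in all 51 cells through NKX2.1.

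**Figure D4:**
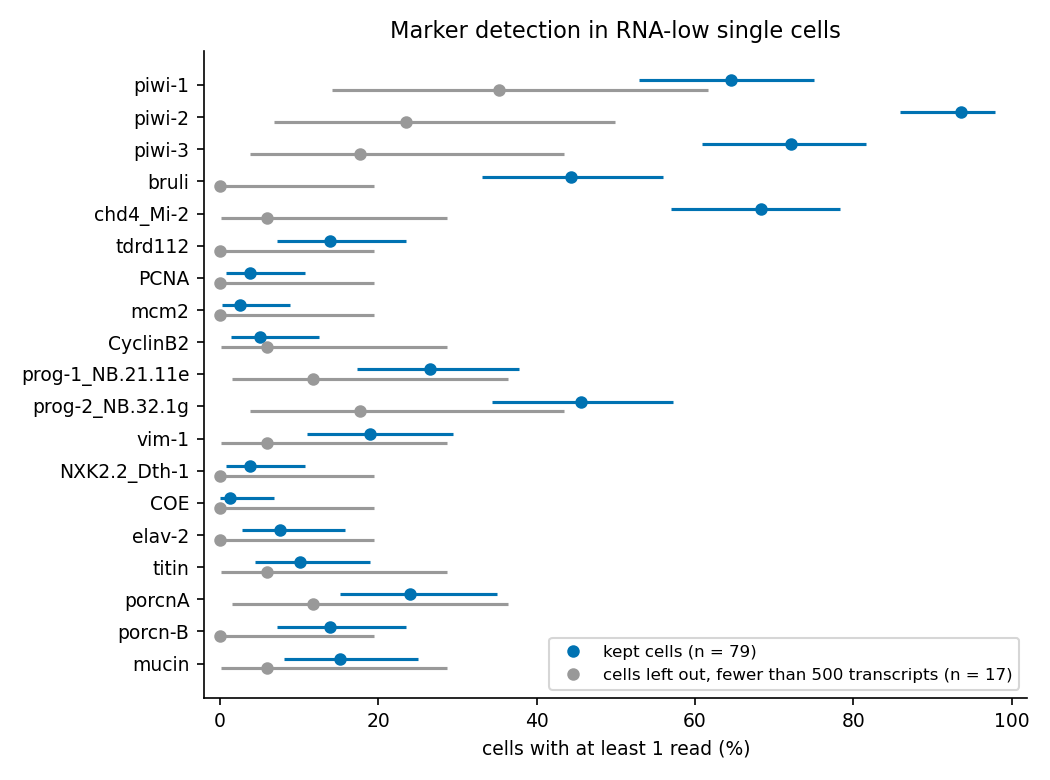
Share of RNA-low single cells with at least 1 read of each marker, in the 79 kept cells and the 17 left out, with exact 95% intervals for counting error. The shares of piwi-2, piwi-3, bruli and chd4 in kept cells lie above those in cells left out, which were set apart by their few detected transcripts, while the intervals of piwi-1 overlap.

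The kept cells formed 3 clusters of 64, 11 and 4 cells, with a low mean silhouette of 0.153 and values from 0.123 to 0.153 over the numbers of clusters tried. With 5 or 20 components, or with CPM of reads other than ribosomal RNA, there were 6 clusters, and with either fewer (500) or more variable transcripts there were 2. Of the 4 cells in the smallest cluster, 2 had 1882 and 6800 reads in all. The clusters differed in depth, with medians of 2235.5, 668 and 1835 detected transcripts. Chd4 was the one named gene among the 8 leading transcripts of any cluster, present in 52 of 64 cells of the first cluster and 2 of the 15 other cells. No cluster had 3 detected markers of a lineage among its leading transcripts, and none was given a cell type name. Across 12702 transcripts, the mean over kept cells had its highest Spearman correlation with the RNA-low bulk library (0.57), followed by PM (0.54), G1 (0.51) and S/G2/M (0.40). With the median over cells PM came first (0.19) and RNA-low next (0.15). Transcripts are not independent replicates, and the library kits differed between cells and bulk.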

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

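Of the tests in this part, those of background reads in the cells and in the bulk library were chosen after the results were seen, and that of ribosomal RNA fragments was written before. A signal outside the bulk comparisons came from 3 transcripts that were read in at least 90 of the 96 cells, with 29641 reads in all, and are not listed in the bulk table.

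A set of 44 transcripts other than ribosomal RNA was read in at least 90 of the 96 cells, and took a median of 86.2% of reads other than ribosomal RNA in the cells left out against 30.3% in the kept cells. Ribosomal RNA fragments counted under other transcripts are argued against only as an account of all 96 cells together. The ratio of these reads to 28S reads had an upper quartile 5.90 times the lower over these cells, where a steady ratio was needed. Kept cells and cells left out were pooled in that ratio, so it cannot decide for the cells left out alone. Reads that did not come from the sorted cell may account for the 44 transcripts. Cells left out held 1.52 times as many of their reads as kept cells (medians of 78429 and 51436), while other reads dropped from 104664 to 13349. This holds for part of the set, as the median of single members in cells left out was at least 0.5 times that in kept cells for 36 of the 44 and below 0.2 times for 7, as for transcripts of the cells themselves. Such reads may also be in the RNA-low bulk library, where 7 transcripts were at least 10-fold above every other gate at 50 CPM or more, and the median of these was present in 100% of the cells left out, against 0% for 3158 other transcripts at that level. An exception was SmedASXL_074105, at 2624 CPM in RNA-low, which was read in 3 of the 17 cells left out. In kept cells the medians were 98.7% for the 7 and 12.7% for the others. Presence in the cells left out therefore does not by itself mark the 7 as background. The 44 transcripts went both ways in that library, with SmedASXL_052632 at 187 CPM (5.95 in G1) and SmedASXL_065734 at 0.707 (1.01 in G1). The 7 made up 1.06% of RNA-low CPM, among them SmedASXL_068163 and SmedASXL_068238 (2628 and 2304 CPM, at most 14.6 and 6.51 elsewhere), chosen after their values were seen. A wider set, of transcripts other than ribosomal RNA read in at least 50% of the cells left out, holds 6 of the 7. Without that wider set the RNA-low against G1 counts were 823 higher and 1148 lower. Where the reads came from, and whether any are biological, was not tested.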

How the results depend on the processing

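Alternatives using fragment intervals, totals or cells without ribosomal RNA, deeper cells, or tables without transcripts of the cells left out were chosen after seeing the data. Over all alternatives 95 main values kept their size and 31 moved. A count of calls kept its size when higher and lower calls together stayed within 1.5 times the main count. The balance of higher and lower calls did not enter, so a count with a turned balance could keep its size. The balance of higher and lower calls turned with median-of-ratios scaling for RNA-low against S/G2/M (2280 and 2767), S/G2/M against PM (3518 and 3056) and S/G2/M against G1 (2116 and 1814), and with a filter of 50 CPM for RNA-low against G1 (208 and 176), RNA-low against PM (592 and 329), S/G2/M against PM (1213 and 453) and S/G2/M against G1 (446 and 404). Of single genes, lists and markers, 2226 values were the same and 416 moved. The counts below are of transcripts called apart, in the order RNA-low against G1, S/G2/M and PM, then G1 against PM, S/G2/M against PM and S/G2/M against G1. With no filter they were 7381, 15760, 17137, 16306, 21331 and 15232, as more transcripts entered. A filter of 50 CPM, which kept fewer, gave 384, 1328, 921, 331, 1666 and 850. A 4-fold threshold gave 550, 1888, 1802, 1104, 2535 and 922. A pseudocount of 5 CPM, which shrinks ratios of weak transcripts, gave 1069, 3154, 2621, 1370 and 2027, S/G2/M against PM staying within 1.5 times. The other scalings kept every count within 1.5 times while moving the balance of higher and lower calls. In single cells, the median number of detected transcripts over all cells was 1803.5. At 5 or more reads, piwi-1 was present in 46.8% of kept cells and accompanied the progeny list in 20.3%. With 5 components, 20 components or CPM of reads other than ribosomal RNA there were 6 clusters, and the cause was not tested. The correlation with RNA-low bulk was 0.56 with no filter, where G1 came before PM, and 0.15 with the median over cells, where PM came first (0.19); the cause was not tested. The PM library, with an estimated 1893544 fragments, limits small differences most, and the 17 cells left out limit what can be told from background.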

Other observations

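The lists in this paragraph were added after the names in the tables had been seen. Of the 33 developmental transcription factors listed, 14 reached 5 CPM in at least 1 gate, and the rest were not counted. Developmental transcription factors were the list furthest above its random lists in RNA-low, with a median log2 ratio, members at 0 reads set to their bound, of 1.56 to G1 (9 of 14 kept members higher, 1 lower), 1.81 to S/G2/M (12 of 13 higher, 1 lower) and 1.71 to PM (9 of 13 higher). Without that bound the percentiles of the medians were 100, 99.9 and 100. The member lower against S/G2/M, klf (-1.07), fell short of 2-fold with library totals (-0.85). With median-of-ratios scaling lmx2 was not called higher against any of the gates. RNA-binding regulators (mex3-1, mex3-3, msi-1 and msi-2) were all higher than in S/G2/M (median 1.98, percentile 99.5), with 1 of 4 higher against G1 (0.68) and PM (0.93), the latter, msi-2 (1.23), falling short of 2-fold with totals without ribosomal RNA (0.94). Wnt pathway genes had medians of 0.79 to G1 (2 of 7 higher), 1.45 to S/G2/M (5 of 8 higher) and 0.85 to PM (3 higher and 1 lower of 8). Hedgehog pathway genes stood at 0.10, 1.05 and 0.77, and 3 of 5 were higher against S/G2/M alone, where the median was 0.88 with median-of-ratios scaling.

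Mediator subunits were called in both directions in S/G2/M against G1, with each scaling. Against S/G2/M, Med12 (3.24) and Med1 (2.48) were higher in RNA-low and Med27 (-1.08) and Med8 (-1.07) lower, for a median of -0.00, but with library totals both lower calls fell short of 2-fold (-0.85 and -0.84), while none of 10 was called against G1 (median 0.33) and 2 were higher against PM (0.57), neither of them with totals without ribosomal RNA. In S/G2/M against G1, Med8 (1.69) and Med27 (1.41) were higher and Med12 (-2.59), Med1 (-1.94) and Med23 (-1.17) lower. Cilia and intraflagellar transport genes had medians of 0.01, 0.05 and 0.30 for RNA-low against G1, S/G2/M and PM, with 3 members lower against G1 and 3 against PM, and 1, FoxJ1-3 (2.31), higher against S/G2/M. The first of these medians changed sign with every other scaling.

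In the hypotheses that follow, the test of neurons was written before its result was seen, although the number of cells with piwi-1 and a neuron marker was already known, and the other tests were chosen after their results were seen. The rule for a verdict in the neuron test was changed after its result was seen.

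By their median, the kept developmental transcription factors stood above G1, S/G2/M and PM in the RNA-low library. Against G1, a general rise of weak transcripts is argued against, since matched random lists had a median of 0.0370 against 1.56. The list had been singled out by its place among such random lists. For S/G2/M and PM this explanation was not tested. Uneven counting of few starting fragments is not excluded for all 9 members called against G1, as the whole fragment interval was at least 2-fold for 8 of them (a share of 0.889) and began at 0.84 on the log2 scale for nerfin-2. Background reads cannot be told apart from expression, as 0.735% of 136 pairs of member and left-out cell held a read (interval 0.0186 to 4.03) and 4.27% of 632 pairs in kept cells (2.83 to 6.16), and the intervals overlap. The pairs cover 8 of the 9 members and are not independent, because members share cells. A lower share is expected for any expressed gene in cells left out for few detected transcripts. Neurons in the gate are not excluded either. Of the kept cells with COE or elav-2, 7 of 7 (59.0 to 100%) held at least 2 pan-neoblast genes at 5 reads or more. So did 79.7% of all kept cells, a share for which the bound set in advance made no allowance. Among 24 kept cells with a read of the factors called higher against G1, 23 did (78.9 to 99.9%), an interval that includes the 79.7%. No marker of mature neurons is named in the tables. A hypothesis that RNA-low neoblasts may express these factors stays open, as it was found and tested on the same libraries, and the single cells are not the cells of the bulk library.

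Within the early epidermal progeny family, 10 of 18 members were highest in G1, 6 in S/G2/M and 2 in PM. Progeny cells carried into the S/G2/M gate from the G1 or PM gate are not excluded. Of the 6 members, 3 (prog-1e, prog-1f and prog-1j) had ratios of at least 2-fold over both gates with each scaling, and fragment intervals above equality. For prog-1j the ratios were 3.53-fold and 7.84-fold. These members were picked for being highest in S/G2/M, and their single levels depend on how reads were divided, so the test cannot decide. Uneven counting of few fragments stays open for prog-1i, since 5 of the 6 members had fragment intervals above equality against both gates and prog-1i did not. Reads shared between near-identical members cannot be told apart from a real difference: the family sum in S/G2/M was 0.216 of that in G1, and how reads of similar copies were divided is not given in the sources used here. A biological difference between the gates may also be present and was not tested.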
